A study of Homo sapiens with 15 samples.

How the data were processed

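Poly(A) RNA was measured by directional paired-end sequencing in 15 libraries from 5 human cell lines, 3 libraries per line. Each library was assigned to its line from the sample label, and all 15 columns of the count table matched a label, with 0 left over. The unit tested was the raw read count per gene that the authors deposited. Per the submitters' processing notes, fastp 0.20.0, HISAT2 2.1.0, featureCounts 1.6.4, SAMtools 1.9, deepTools 3.2.0 and DESeq2 1.28.1 were used with genome build hg38. Those notes give no role, order or setting for any of them, and whether the counting used strand is not stated. The authors also deposited a table of normalised signal, which equals the raw count divided by 1 size factor per library (largest relative difference from a recomputed median-of-ratios factor 2e-09). It served only for that check. A further deposited table on a log scale was not used, because its transformation is not stated and the raw counts carry the depth.

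The count table held 15517 rows, of which 7 are sequences of the transfected constructs and 15510 are genes. The smallest row total over the 15 libraries was 10 reads, so rows under that total are not in the table. Gene symbols came from the table itself, 9 gene rows had none, and 15502 gene rows were placed on the deposited protein-coding annotation, which holds 19976 genes. The construct rows were left out of the main fit and out of the library sizes, since the reads of a human construct and of the cell's own gene may be counted on either. For the same reason, values of the genes TERT, CCND1, CDK4, HRAS and AKT1 are uncertain in lines that carry the construct. Overlapping or antisense genes cannot be separated if strand was not used in counting, and in the deposited annotation the spans of CCND1, CDK4, MAP2K1, CDKN2A and MDM2 overlap a gene on the other strand and that of BUB1B a gene on its own strand.

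Reads counted on genes ranged from 20.63 to 46.55 M reads per library. Levels are given as CPM (counts scaled to library size) computed here from the deposited counts with trimmed-mean (TMM) factors, as a mean with the SD over 3 libraries. A gene with no read in a group was given the floor of 3 reads over that group's libraries, and the fold is then written as at least that size. A gene with 1 to 3 reads in a group is given as a ratio of CPM with its 95% exact binomial interval. Reads carry no molecular identifiers, so such intervals and floors cover counting error only.

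Genes were filtered with filterByExpr by line (minimum count 10), which left 13599. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, glmQLFit and glmQLFTest) on all 15 libraries with the line as the sole factor, and 7 comparisons were drawn from the fit. Adjusted p-values are Benjamini-Hochberg values over the 13599 genes of a comparison, and a gene counts as called under 0.05. Log2 fold changes and their SE are edgeR's. Because every replicate of a line came from its own freshly thawed vial passaged 2 times, per the labels, the p-values compare these lines with the spread between vials, cultures and preparations. They do not cover independently transfected lines, of which there is 1 per construct.

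The 25 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and a variance trend, with Benjamini-Hochberg adjustment over the 25 lists within a comparison. Beside it stands the same test with the correlation estimated per list from the residuals. The lists were construct genes, ERK pathway output, EGFR family ligands, p53 targets, DNA replication and S phase, spindle assembly checkpoint, kinetochore and centromere, spindle and cytokinesis, mitotic kinases with passengers and chromosome structure, retinal pigment epithelium identity, mesenchymal and contractile genes, epithelial junction and keratin, collagen and matrix, YAP and TEAD targets, matrix proteases and the plasminogen system, inflammatory cytokines and NF-kB, interferon response, class I antigen presentation, glycolysis and hypoxia, sterol and fatty acid synthesis, FOXO targets, ATF4 and amino acid response, ribosome biogenesis and MYC targets, TGF-beta and BMP response, and markers of other cell types. Lists, design, alternatives and the rule for named genes were fixed before the data were examined. That rule took 19 genes in every comparison, namely the 7 construct genes with BUB1, BUB1B, KNL1, TTK, AURKA, AURKB, CDKN1A, CDKN2A, DUSP6, SPRY4, FOSL1 and MYC. It added the 8 largest rises and 8 largest falls in comparisons against T53D4 or ARPE19, and the 5 largest each way in the others, among called genes with a mean of at least 5 CPM in the higher line and no overlap between replicates. Up to 3 called members per list, those with the largest log2 fold change, completed it. Some genes that the rule selects are not reported here. The same camera test was run on the genes of each chromosome, with adjustment over chromosomes.

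Replicate numbers were tested for pairing by correlating the deviations of same-numbered libraries from their line means. All 3 correlations exceeded the threshold of 0.1 in 6 of the 7 comparisons, from 0.14 to 0.64. Libraries with different numbers correlated on average between -0.24 and -0.13 in those comparisons. Deviations within a line cancel out, so these negative values follow from the positive ones and add no evidence of pairing. In those 6 the fit with the replicate number as a block is given beside the printed genes, lists and counts wherever it changes a call or moves a count by over 1.5 times. The pairing is read from the data alone, as the labels name no shared day or batch. Calls shared by 2 lines against T53D4 were set beside the product of independent lists and beside 20 simulations of unchanged lines sharing 3 T53D4 libraries, in which the libraries of T53D4 and of the 3 oncogene lines were all drawn from the T53D4 means.

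The alternatives were DESeq2 1.42.0, RLE size factors in edgeR, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, the 2 lines of a comparison alone, the replicate block, glmTreat against 1.5-fold, a robust dispersion, and leaving out each library in turn. Lists were also tested with fry, with the block and without the construct genes. Keeping the construct rows, leaving out the 5 libraries numbered replicate 1, and the chromosome test with the block were added after the data were seen. RLE and DESeq2 size factors moved the median log2 fold change of all genes by less than 0.1 in every comparison. For T53D4 versus ARPE19 the share of called genes that were higher was 23.8% with TMM, 23.8% with RLE factors in edgeR and 41.1% with DESeq2.

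The edgeR fit was tested for 2 of the comparisons on simulated counts for the 13599 genes with 200 changed genes, 1 of which fell in the shifted list and was not scored. For T53D4 versus ARPE19 it recovered 8 of 67 genes changed 1.5-fold, 30 of 67 changed 2-fold and 61 of 65 changed 4-fold, with 5 unchanged genes called. For RasV12 versus T53D4 it recovered 7 of 66, 35 of 67 and 61 of 66, with 7 unchanged genes called. The simulated shifted list was recovered in both and 0 other lists were called. Simulated genes were drawn independently and without paired replicates, so this cannot show how camera behaves on genes that vary together. Trends on GC content and exon length used mgcv 1.9.3, with the GC content of each gene's longest transcript from a GENCODE transcript set of the same build and exon length from the deposited annotation. Figures were drawn with matplotlib 3.10.9 in python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.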

Results

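The libraries come from ARPE19, an established human retinal pigment epithelial line, and from 4 lines made from it, with 3 libraries per line. T53D4 is labelled as carrying hTERT with p53DD, a dominant negative fragment, and cyclin D1 with CDK4R24C, a CDK4 mutant. RasV12, MekDD and AKTmyr are labelled as carrying those plasmids plus an active H-RAS, an active MEK or a membrane-bound AKT. The labels call ARPE19 and T53D4 not transformed, MekDD weakly transformed and the other 2 transformed. Reads on genes (M reads, replicates 1, 2 and 3) were 35.24, 39.55 and 24.02 in ARPE19, 30.5, 44.6 and 20.63 in T53D4, 27.39, 41.69 and 22.24 in RasV12, 32.74, 36.95 and 22.9 in MekDD, and 37.98, 46.55 and 24.05 in AKTmyr.

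**Figure D1:**
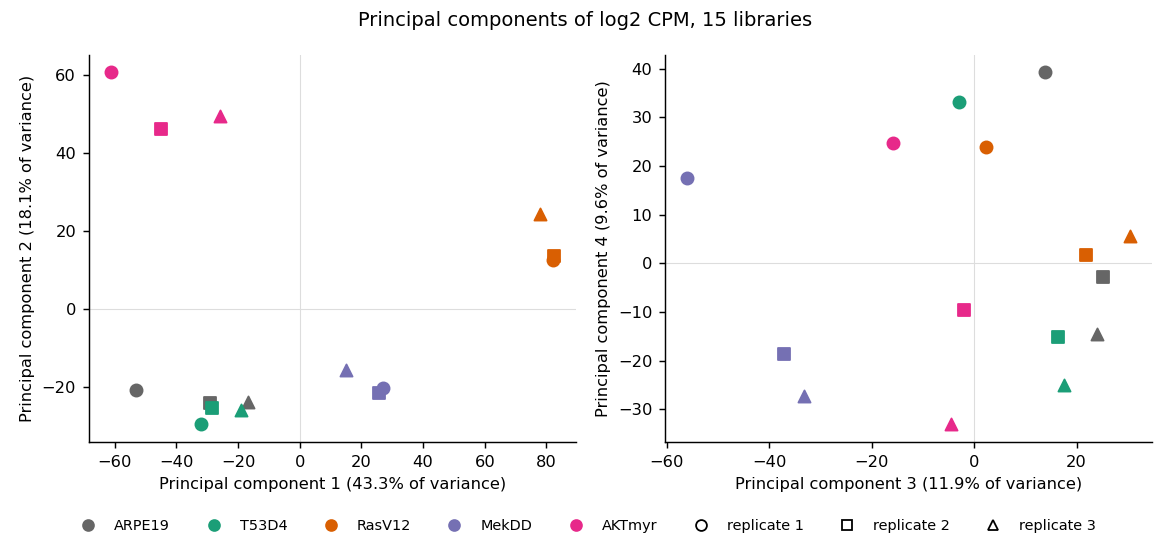
Principal components 1 and 2 (left) and 3 and 4 (right) of log2 CPM for the 15 libraries, with colour for the line and shape for the replicate number. Component 1 (43.3% of variance) places RasV12 highest, and component 4 (9.6%) places the replicate 1 libraries, from 17.45 to 39.25, above all others, from -33.07 to 5.66.

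The transfected genes were examined first, since they check the labels. RasV12 held 310 ± 30.4 CPM (SD, n = 3) on the HRASV12 construct against 20.8 ± 3.69 in T53D4, MekDD held 753 ± 229 on MEKDD against 4 reads over the 3 T53D4 libraries, and AKTmyr held 840 ± 334 on the AKT construct against 117 ± 16. Every line other than ARPE19 carried TERT construct reads, from 454 ± 58.2 CPM in MekDD to 1244 ± 66.4 in RasV12, against 0.176 in ARPE19. The murine p53DD construct had 70.7 ± 20.1 CPM in T53D4, 111 ± 12.4 in RasV12, 32.3 ± 8.36 in MekDD and 58.4 ± 20.1 in AKTmyr, and 1 read in ARPE19. The cyclin D1 and CDK4 constructs went against the labels of T53D4. Their log2 differences from ARPE19 were -0.40 (SE 0.21) and 0.38 (SE 0.15), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.511 and 0.382. The CDK4R24C construct stood at 70.7 ± 12 CPM in ARPE19, 92.2 ± 11.8 in T53D4, 142 ± 13.7 in MekDD, 1006 ± 90.1 in AKTmyr and 2380 ± 23.3 in RasV12. Those libraries are therefore written below as the libraries labelled T53D4, or T53D4 for short, and the same holds for MekDD. Its reads on both constructs exceeded T53D4 by log2 0.89 (SE 0.21) and 0.62 (SE 0.15), but their ratios to the reads on the CCND1 and CDK4 genes, 0.247 and 1.105, lay near those of ARPE19, 0.231 and 1.064. ARPE19, labelled as untransfected, holds reads on both as well, so a level near its own does not show a plasmid.

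**Figure D2:**
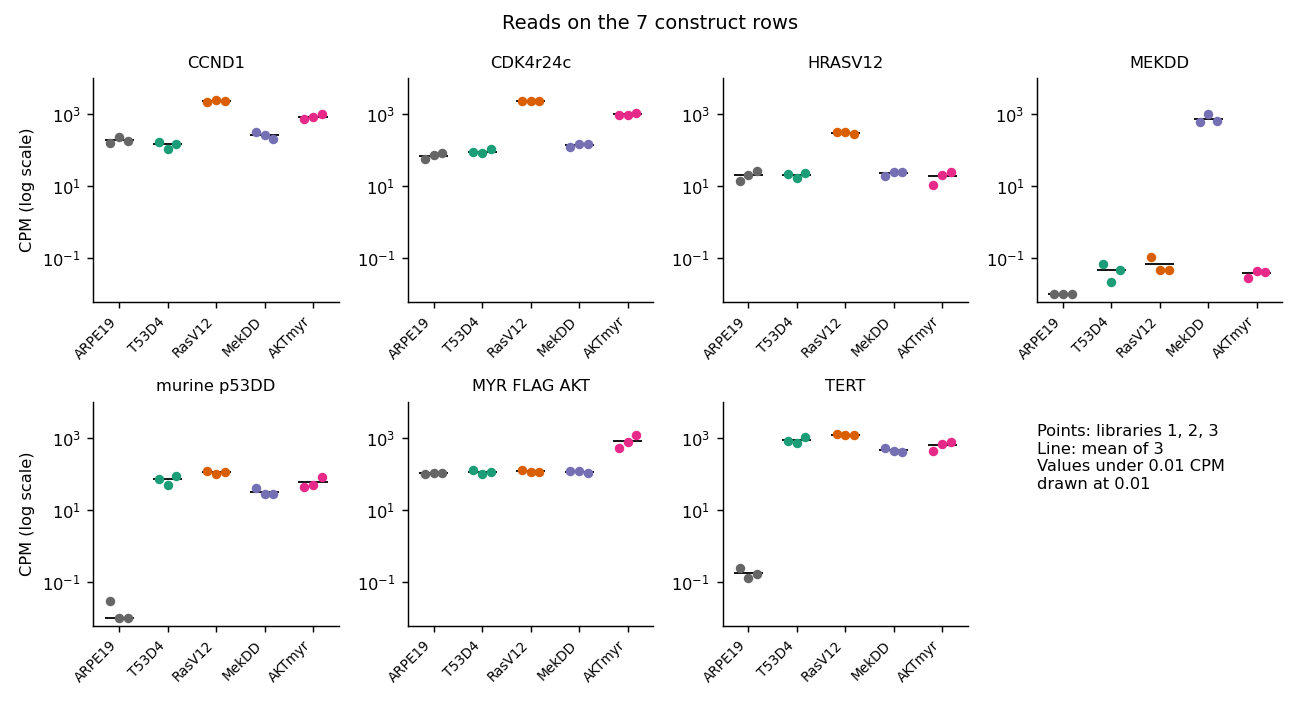
CPM on a log axis for the 7 construct sequences, with a point per library and a line at the mean of 3, and values under 0.01 drawn at 0.01. The CCND1 and CDK4 panels show T53D4 (145.8 and 92.22 CPM) near ARPE19 (193 and 70.73 CPM), and RasV12 and AKTmyr far above both.

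T53D4 versus ARPE19 asks what the immortalising constructs change before an oncogene is added. Members of the p53 targets list were lower. RRM2B, a ribonucleotide reductase subunit, stood at 84.5 ± 3.71 CPM in T53D4 and 184 ± 15.5 in ARPE19, SESN1, a stress-response gene, at 16 ± 1.7 and 37.2 ± 5.29, and MDM2, a ubiquitin ligase gene, at 62.1 ± 14.1 and 154 ± 11.7 (SD, n = 3 throughout). PHGDH, which opens serine synthesis, was higher, at 382 ± 79.8 CPM against 134 ± 43.5. TERT rose by log2 11.95 (SE 0.32, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.34e-11), on a gene that shares reads with its construct.

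Of 25 measured p53 targets, 3 fell, 0 rose and 22 did not pass the test, and 18 fell when adjusted over the list alone. Their median log2 fold change was -0.64, and 24 of 25 had a negative value (camera, Benjamini-Hochberg adjusted p = 3.89e-21, and adjusted p = 0.0349 with an estimated correlation). MDM2 (ENSG00000135679, chromosome 12, 68808177 to 68850686) fell by 1.31 on the log2 scale (SE 0.22), SESN1 by 1.22 (SE 0.18) and RRM2B by 1.13 (SE 0.15), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0399, 0.0302 and 0.0196. CDKN1A, the p21 cell cycle inhibitor, had a log2 difference of -1.38 (SE 0.28, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0966, and 0.02 with the replicate block). Of 25 genes of the ATF4 and amino acid response, PHGDH rose (log2 1.52, SE 0.24, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0355) and 24 did not pass, and 18 rose when adjusted over the list alone (median 0.98, camera, Benjamini-Hochberg adjusted p = 2.48e-17, and adjusted p = 0.174 with an estimated correlation). With the block, 12 p53 targets were called lower, 7 ATF4 genes higher, and the p53 list had adjusted p = 0.187 with an estimated correlation.

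Cell division genes had small positive values with no member called over all genes, and with the replicate block 2 replication genes, 1 kinetochore gene and 1 mitotic kinase gene were higher. The DNA replication list (37 genes) had a median of 0.62 with all 37 values above 0, and 3 rose when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.48e-17, and adjusted p = 0.326 with an estimated correlation). Kinetochore genes (33) had a median of 0.43 and mitotic kinases with their partners (27) one of 0.36, with 0 and 5 rises when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.98e-12 and 1.96e-09), and adjusted p = 0.332 and 0.353 with an estimated correlation. The spindle and cytokinesis list (26 genes, 0.23) and the spindle checkpoint list (13 genes, 0.17) passed camera with Benjamini-Hochberg adjusted p = 2.74e-04 and 0.0139, with no member called either way, and adjusted p = 0.55 and 0.562 with an estimated correlation. AURKB, a chromosomal passenger kinase, stood at 61.4 ± 4.51 CPM against 34.7 ± 7.6 (log2 0.83, SE 0.20, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.139), and BUB1, a checkpoint kinase, at 120 ± 10.4 against 120 ± 43.2. Glycolysis and hypoxia genes (29) had a median of -0.48 with no calls, and 1 lower with the block (camera, Benjamini-Hochberg adjusted p = 5.33e-07, and adjusted p = 0.339 with an estimated correlation). ERK output, EGFR ligand and epithelial genes had medians of -0.18, -0.46 and -0.36 with no calls, and 1, 1 and 0 lower with the block (camera, Benjamini-Hochberg adjusted p = 0.00373, 0.0159 and 0.00801, and adjusted p = 0.175, 0.326 and 0.326 with an estimated correlation). Class I presentation, sterol synthesis and ribosome biogenesis genes had medians of 0.15, 0.16 and 0.13 with no calls (camera, Benjamini-Hochberg adjusted p = 0.0099, 0.00373 and 0.0235, and adjusted p = 0.55, 0.55 and 0.634 with an estimated correlation). With the block the protease and interferon lists passed as well (adjusted p = 0.035 and 0.0416, and adjusted p = 0.433 and 0.595 with an estimated correlation). CDK4 passed with the block too (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0335). The replication list's median ranged from -0.91 to 0.07 among the ARPE19 libraries, lowest in replicate 1. Without the replicate 1 libraries, a choice made after seeing the data, the spindle, checkpoint, class I presentation, sterol and ribosome biogenesis lists missed the test (adjusted p = 0.0944, 0.394, 0.0899, 0.0759 and 0.63).

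In all, 5 genes were higher and 16 lower in T53D4 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1456 had an unadjusted p under 0.05. With the replicate block the counts were 101 and 131. All but the TERT call were lost in some fits with a single library left out. All 21 were kept with the replicate block and with DESeq2, and 2 with the 2 lines alone. Without ARPE19 replicates 1, 2 or 3 the counts were 1 and 2, 1 and 0, and 1 and 5, without T53D4 replicates 1, 2 or 3 they were 1 and 0, 1 and 0, and 3 and 1, and MDM2, SESN1, RRM2B and PHGDH each lost the call in some of these fits, with adjusted p from 0.0509 to 0.192. Directions here rest on libraries in which the cyclin D1 and CDK4 constructs did not match the T53D4 label.

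RasV12 versus T53D4 asks what active RAS adds. Feedback genes switched on by ERK, the last kinase of the RAS pathway, rose. DUSP6 (ENSG00000139318, chromosome 12, 89347235 to 89352501), an ERK phosphatase, stood at 351 ± 50.5 CPM in RasV12 and 7 ± 1.01 in T53D4, and SPRY4 (ENSG00000187678, chromosome 5, 142310427 to 142326455), a RAS pathway inhibitor, at 111 ± 33.7 and 2.81 ± 1.39 (SD, n = 3). The collagenase MMP1 rose from 0.342 ± 0.167 to 3500 ± 1480 CPM, and the cytokine IL33 from 0.401 ± 0.274 to 509 ± 389. Genes of the spindle checkpoint, kinetochore and spindle, by contrast, gave 1 rise and 2 falls among 72 measured, and 3 rises and 4 falls with the replicate block.

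Of 23 ERK output genes, 18 rose, 0 fell and 5 did not pass, with 18 and 0 when adjusted over the list alone. Their median was 1.73 (camera, Benjamini-Hochberg adjusted p = 1.06e-13, and adjusted p = 0.00226 with an estimated correlation). DUSP6 had a log2 fold change of 5.65 (SE 0.22), SPRY4 one of 5.28 (SE 0.39) and HMGA2, a chromatin protein, one of 3.24 (SE 0.30), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.48e-09, 7.01e-07 and 5.76e-06. FOSL1, an AP-1 subunit, rose by 1.07 (SE 0.23, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00405). Among 16 proteases and plasminogen genes 10 rose and 3 fell, over all genes and over the list alone (median 1.92, camera, Benjamini-Hochberg adjusted p = 0.00185, and adjusted p = 0.0866 with an estimated correlation), led by MMP1 (log2 13.43, SE 0.86), MMP3 (9.13, SE 1.97) and MMP10, which had no read in T53D4 and was at least 38.3-fold higher. Cytokine genes split, with 9 of 20 higher and 1 lower on both adjustments (median 0.62, camera, Benjamini-Hochberg adjusted p = 0.00682, and adjusted p = 0.746 with an estimated correlation). IL33 and IL1B rose by log2 10.44 (SE 0.76) and 8.75 (SE 0.91), and CCL2 fell by 9.60 (SE 1.15). The cytokine median was 0.76, 0.20 and 1.95 in RasV12 replicates 1, 2 and 3, so the size varied between libraries. EGFR ligands gave 3 rises among 6, and 3 rises and 1 fall with the block, led by AREG (log2 4.26, SE 0.66), with camera, Benjamini-Hochberg adjusted p = 0.12.

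Falls outnumbered rises in the matrix, junction and pigment epithelium lists. Collagen and matrix genes gave 12 falls and 2 rises among 23, and 13 and 3 when adjusted over the list alone (median -1.01, camera, Benjamini-Hochberg adjusted p = 0.0124, and adjusted p = 0.713 with an estimated correlation), with COL5A1 down by log2 -4.76 (SE 1.05) and COL6A3 up by 8.65 (SE 0.77). Epithelial junction genes gave 10 falls and 2 rises among 19 on both adjustments, YAP targets 8 and 2 among 16 (9 and 2 over the list alone) and FOXO targets 10 and 3 among 20 (12 and 3 over the list alone), with camera, Benjamini-Hochberg adjusted p = 0.00316, 0.0257 and 0.00316, and adjusted p = 0.379, 0.381 and 0.386 with an estimated correlation. Examples are LAMA3, a laminin chain (log2 -3.78, SE 0.40), CRIM1 (-1.79, SE 0.30) and the ubiquitin ligase gene FBXO32 (-1.65, SE 0.34). Of 17 retinal pigment epithelium genes 6 fell and 0 rose, 6 and 1 over the list alone, and 7 and 2 with the block (median -0.70, camera, Benjamini-Hochberg adjusted p = 0.0562), among them MITF, the pigment cell regulator, at 27.5 ± 3.26 CPM against 92.5 ± 22.9. Sterol synthesis genes gave 8 falls and 1 rise among 32, and 9 and 2 over the list alone and with the block (camera, Benjamini-Hochberg adjusted p = 0.0476, adjusted p = 0.821 with an estimated correlation, and 0.0514 once the construct genes were taken out of the lists).

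Lists whose camera test was not passed were mesenchymal genes (3 rises and 7 falls among 17, 5 and 7 with the block), interferon response (4 and 8 among 26), class I presentation (0 and 3 among 17), p53 targets (5 and 3 among 25), TGF-beta response (6 and 3 among 21, 9 and 5 with the block), ATF4 response (1 and 4 among 25, 2 and 6 with the block), glycolysis (3 and 2 among 29, 5 and 4 with the block), ribosome biogenesis (3 and 1 among 26) and markers of other cell types (2 and 3 among 8 measured of 22). The construct genes passed (3 rises and 1 fall among 7, camera, Benjamini-Hochberg adjusted p = 0.015, and adjusted p = 0.381 with an estimated correlation), on reads shared with the constructs. For cell division, the replication list had a median of -0.02, kinetochore 0.21, checkpoint 0.25, spindle 0.11 and mitotic kinases 0.06, with camera, Benjamini-Hochberg adjusted p from 0.291 to 0.981. The replication list gave 0 rises and 1 fall and the mitotic kinases 0 and 1, with the block 3 and 2, and 0 and 2. BUB3, a checkpoint protein encoded on chromosome 10, rose by log2 0.81 (SE 0.18, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00531), while BUB1 (0.29, SE 0.24), TTK (0.21, SE 0.30), KNL1 (0.38, SE 0.29), AURKB (-0.01, SE 0.20) and AURKA (0.66, SE 0.27) did not pass. AURKA passed without RasV12 replicate 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0497). CDKN1A rose from 191 ± 26.1 to 491 ± 104 CPM, and CDKN2A, the p16 and ARF gene, fell by log2 -1.18 (SE 0.26).

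The largest rises besides MMP1 and IL33 were PI3, LCE1F, SNAP25 and HSD11B1, with no reads in T53D4 and at least 1100-fold, 299-fold, 269-fold and 183-fold higher, TREM1 (ratio 6190, 95% interval 1110 to 244000) and STC1 (847, 290 to 4110). The largest falls were ITM2A, with no reads in RasV12 and at least 280-fold lower, GALNT17 (ratio 1250, 345 to 10300), CCL2, NPPB (log2 -9.41, SE 1.03), GABRA5 (ratio 493, 88.2 to 19500), ALKAL2 (459, 82 to 18200), FAM110C (log2 -7.67, SE 0.71) and KLK11 (-7.50, SE 0.79). PI3 varied widely between libraries (34.3 ± 56.5 CPM). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1466 genes were higher and 1847 lower in RasV12, 642 and 1079 of them by 2-fold or more. With the replicate block 2259 genes were higher, and the libraries labelled T53D4 serve as reference despite their cyclin D1 and CDK4 signal, so this comparison also spans log2 4.01 (SE 0.23) and 4.69 (SE 0.17) in those constructs.

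Along chromosome 10 the RasV12 line differed by arm, a feature chosen after its values were seen. The genes parted at the widest stretch without genes, 38360099 to 42574184. The 102 genes of the short arm with a mean of at least 5 CPM had a median log2 fold change of -0.33 against T53D4 (42 fell, 3 rose), and the 329 of the long arm one of 0.31 (99 rose, 31 fell). In MekDD and AKTmyr the medians of both arms lay between -0.01 and 0.07. Chromosome 20 genes (352) had a median of 0.23 and those of chromosome 22 (305) one of -0.17 (camera, Benjamini-Hochberg adjusted p = 3.60e-04 and 0.00235, and adjusted p = 0.446 and 0.654 with an estimated correlation). In MekDD and AKTmyr against the same T53D4 libraries the medians were -0.04 and 0.00 for chromosome 20 and -0.11 and -0.08 for chromosome 22. Against MekDD, RasV12 had a chromosome 20 median of 0.30 (84 higher, 11 lower, camera, Benjamini-Hochberg adjusted p = 3.11e-08, and adjusted p = 0.067 with an estimated correlation). BUB3 lies on the long arm of chromosome 10, and AURKA, BMP2 and MYBL2 on chromosome 20.

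**Figure D3:**
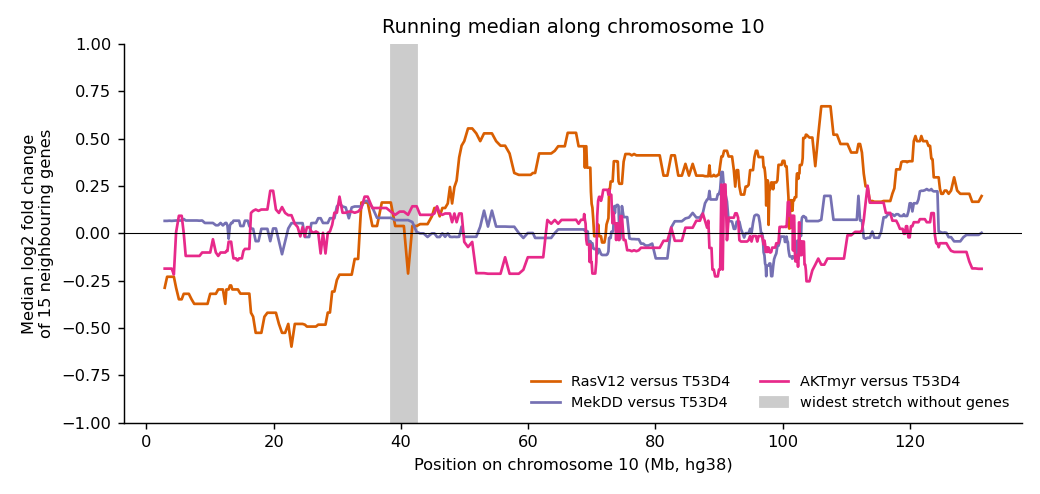
Median log2 fold change of 15 neighbouring genes along chromosome 10 (Mb, hg38) for the 3 oncogene lines against T53D4, with the widest stretch without genes in grey. RasV12 runs below 0 over most of the short arm (median -0.33) and above 0 over most of the long arm (0.31), and the other lines stay near 0.

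MekDD versus T53D4 asks what active MEK adds, although other constructs differed between these lines as well. The same 2 feedback genes rose, to lower levels than in RasV12. DUSP6 stood at 84.6 ± 12.5 CPM against 7 ± 1.01, SPRY4 at 31 ± 5.79 against 2.81 ± 1.39, and MMP1 at 87.9 ± 64.3 against 0.342 ± 0.167 (SD, n = 3). KRT7, a simple epithelial keratin, fell from 1330 ± 346 to 32.9 ± 6.31 CPM, and the gelatinase MMP2 from 36 ± 14.8 to 3.02 ± 1.27.

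Of 23 ERK output genes 8 rose, 0 fell and 15 did not pass, with 14 rises when adjusted over the list alone and 13 with the replicate block. The median was 0.90 (camera, Benjamini-Hochberg adjusted p = 8.87e-14, and adjusted p = 0.00221 with an estimated correlation). DUSP6 rose by log2 3.60 (SE 0.20), SPRY4 by 3.44 (SE 0.36) and PHLDA1 by 1.96 (SE 0.27), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.85e-07, 6.13e-05 and 5.38e-04. FOSL1 had a log2 difference of 0.46 (SE 0.23, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.329). Sterol and fatty acid synthesis genes gave 7 falls and 0 rises among 32, 14 falls over the list alone and 12 with the block (median -0.49, camera, Benjamini-Hochberg adjusted p = 1.64e-08, and adjusted p = 0.657 with an estimated correlation). HMGCS1, the mevalonate pathway's entry enzyme, stood at 83.7 ± 6.75 CPM against 175 ± 31, and its call was lost without any 1 of the 6 libraries. Proteases gave 5 rises and 1 fall among 16, and 8 and 2 over the list alone and with the block (camera, Benjamini-Hochberg adjusted p = 0.0177, adjusted p = 0.26 with an estimated correlation, and 0.0535 without the replicate 1 libraries). The other 22 lists did not pass, and the p53 targets passed with the block (camera, Benjamini-Hochberg adjusted p = 0.0626, 0.0451 with the block, and adjusted p = 0.998 with an estimated correlation and the block). Checkpoint, kinetochore, spindle and replication lists had medians of 0.09, 0.05, 0.03 and 0.02 with no member called, and of 27 mitotic kinase genes MYBL2 alone fell, a call lost without any 1 of the 6 libraries.

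Among the largest rises were STC1 (ratio 435, 95% interval 148 to 2110), DMBT1 (450, 154 to 2180), MMP1 (log2 8.12, SE 0.75), ALDH1A1 (6.72, SE 1.22), PLXNA4 (6.05, SE 0.64), KIAA1549L (5.92, SE 0.36) and NGEF (5.18, SE 0.54). Among the largest falls were ITM2A (ratio 419, 116 to 3460), HEPH (log2 -7.91, SE 0.54) and GPC4 (-6.06, SE 0.49). RAX, an eye field regulator, fell too (ratio 270, 74.4 to 2240), as did CPXM2 and KLK11. KRT7 fell by log2 -5.34 (SE 0.47) and MMP2 by -3.57 (SE 0.41), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.15e-05 and 1.13e-04. Of the 11 tested genes of chromosome Y 8 fell and 3 rose (median -4.83), and of 305 on chromosome 22 10 fell and 1 rose (median -0.11), with camera, Benjamini-Hochberg adjusted p = 3.02e-08 and 0.0367, and adjusted p = 0.146 and 0.423 with an estimated correlation. CDK4 and MYC missed the test and passed with the block (log2 0.45 and -0.43, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0968 and 0.179, with the block 0.013 and 0.0479).

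By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 309 genes were higher and 385 lower in MekDD, and 746 and 843 with the replicate block. Without T53D4 replicate 2 the counts were 175 and 222, without MekDD replicate 1 they were 202 and 197, and without MekDD replicate 2 they were 170 and 190. Both lines of this comparison hold less cyclin D1 and CDK4 construct signal than the other oncogene lines, against their labels. MekDD held less p53DD and TERT construct signal than T53D4 (log2 -1.13, SE 0.26, and -0.95, SE 0.2). It held more cyclin D1 and CDK4 construct signal (0.89, SE 0.21, and 0.62, SE 0.15). All 4 were called (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p from 0.0112 to 0.0233), so the comparison does not isolate MEK.

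AKTmyr versus T53D4 asks what active AKT adds, and here ERK output went down. SPRY4 stood at 0.548 ± 0.219 CPM against 2.81 ± 1.39, DUSP6 at 3.83 ± 0.611 against 7 ± 1.01, and MYC, a growth regulator, at 86.1 ± 11.9 against 212 ± 21.9 (SD, n = 3). CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339) rose from 191 ± 26.1 to 1020 ± 388 CPM. MMP2 rose from 36 ± 14.8 to 325 ± 128, and CA12, a hypoxia-linked carbonic anhydrase, from 14.3 ± 0.977 to 62.6 ± 12.2.

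Of 23 ERK output genes 15 fell, 0 rose and 8 did not pass, with 16 falls over the list alone (median -0.89, camera, Benjamini-Hochberg adjusted p = 1.60e-07, adjusted p = 0.0286 with an estimated correlation, and 0.151 with an estimated correlation and the block). ETV4, DUSP5 and SPRY4 fell by 2.49 (SE 0.42), 2.18 (SE 0.30) and 2.30 (SE 0.42) on the log2 scale, with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00157, 3.84e-04 and 0.00258. FOSL1 fell by 0.92 (SE 0.23, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0145), a call lost without T53D4 replicate 1 (0.0574). Glycolysis and hypoxia genes gave 14 rises and 0 falls among 29, 18 over the list alone and 24 with the block, and all 29 values lay above 0 (median 0.97, camera, Benjamini-Hochberg adjusted p = 1.92e-08, and adjusted p = 0.629 with an estimated correlation). EGLN3, an oxygen-sensing hydroxylase, rose by log2 2.82 (SE 0.61) and CA12 by 2.13 (SE 0.22). The glycolysis median differed between the T53D4 libraries, at 0.15, -0.89 and -0.28. Ribosome biogenesis and MYC targets gave 18 falls and 0 rises among 26, 22 over the list alone (median -0.67, camera, Benjamini-Hochberg adjusted p = 1.14e-09, and adjusted p = 0.629 with an estimated correlation), with MYC down by log2 -1.30 (SE 0.17), RRS1 by -1.18 (SE 0.25) and NOP16 by -0.99 (SE 0.21). The list's median was -0.90, -0.40 and -0.31 in AKTmyr replicates 1, 2 and 3, and 9 genes fell without the replicate 1 libraries.

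DNA replication genes gave 4 falls and 0 rises among 37, 2 over the list alone and 13 with the block (median -0.46, camera, Benjamini-Hochberg adjusted p = 1.30e-04, and adjusted p = 0.926 with an estimated correlation), led by CDT1, a licensing factor (log2 -0.99, SE 0.18). Their median in AKTmyr replicates 1, 2 and 3 was -0.84, -0.30 and 0.35, a spread larger than the difference between the lines. In T53D4 replicates 1, 2 and 3 it was 0.13, 0.12 and 0.50, so AKTmyr lay lower in each same-numbered pair. The mitotic lists did not pass, with medians from -0.27 to -0.18 and 1 rise and 1 fall among 99 genes, and 1 and 4 with the block. Class I presentation genes gave 3 rises among 17, and 7 with the block (median 0.40, camera, Benjamini-Hochberg adjusted p = 0.049, adjusted p = 0.926 with an estimated correlation, and 0.0641 with the block). Collagen genes gave 5 rises and 1 fall among 23, and 11 and 2 with the block (median 0.67, camera, Benjamini-Hochberg adjusted p = 0.058, 0.0213 with the block, and adjusted p = 0.97 with an estimated correlation and the block). Median, mean and test differed in sign for 5 lists that did not pass, namely construct genes (median -0.20, mean 0.56), ATF4 response (-0.06, 0.19), FOXO targets (-0.04, 0.12), mesenchymal genes (0.01, -0.38) and epithelial genes (0.21, 0.24, tested lower).

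Among the largest rises were IGF1 (ENSG00000017427, chromosome 12, 102395874 to 102481744), a growth factor with no reads in T53D4 and at least 228-fold higher, CDH18 (log2 6.48, SE 0.69), ACTC1 (6.20, SE 0.86), CACNB4 (5.74, SE 0.46), KRT16 (5.44, SE 0.81), CLEC19A (5.42, SE 1.07) and RAB7B (5.20, SE 0.54). Among the largest falls were KIF1A (-7.60, SE 0.47), RAX (ratio 201, 95% interval 68.6 to 980), NPPB (log2 -4.81, SE 0.78), ALKAL2 (-4.48, SE 0.91) and LHX2 (-4.25, SE 0.24). CDKN1A rose by 2.41 (SE 0.29), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.72e-04. BUB1, BUB1B, TTK, KNL1, AURKA and AURKB did not pass, with log2 values from -0.53 to 0.15. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1347 genes were higher and 1391 lower in AKTmyr, and 2304 and 2434 with the replicate block. Without T53D4 replicate 3, 812 were higher, without AKTmyr replicate 1 the counts were 818 and 793, and without all replicate 1 libraries 816 were lower. As with RasV12, this comparison spans the cyclin D1 and CDK4 constructs (log2 2.56, SE 0.22, and 3.45, SE 0.16), which stood near the ARPE19 level in the libraries labelled T53D4.

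**Figure D4:**
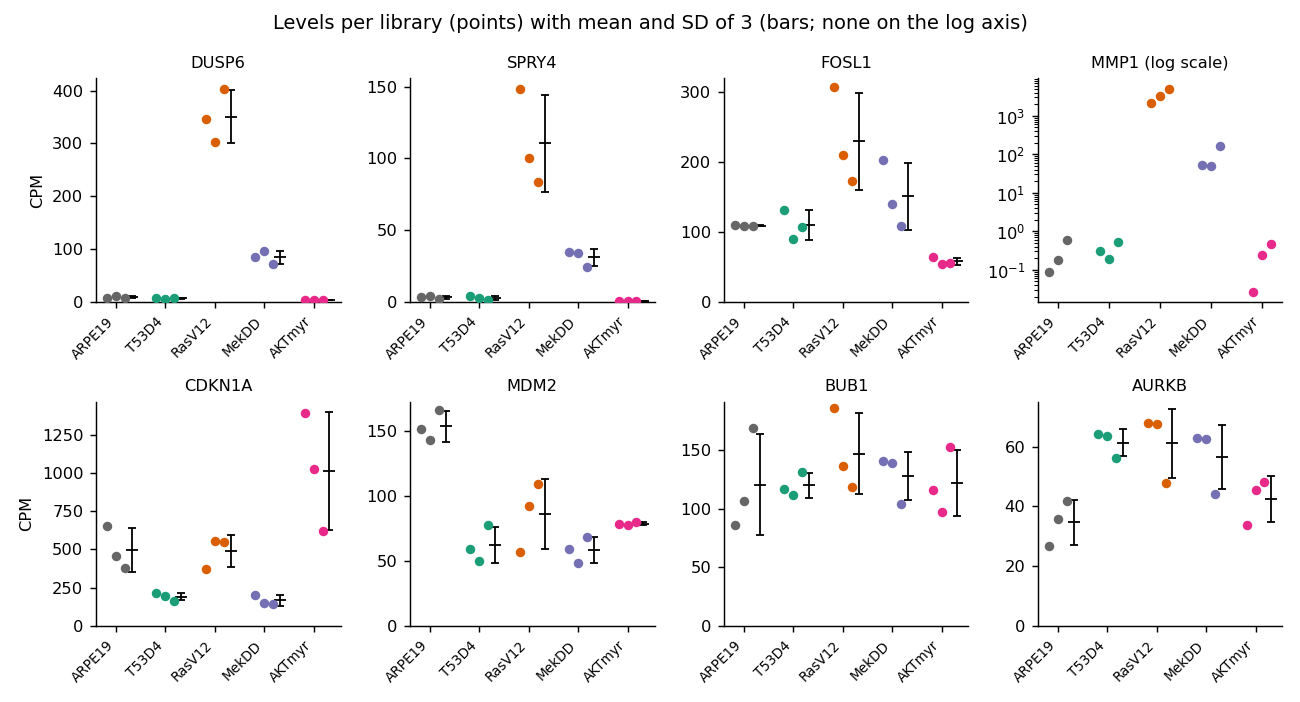
CPM of 8 genes in each of the 15 libraries (points) with the mean and SD of 3 (bars, not drawn for MMP1, whose axis is logarithmic). DUSP6 averages 351 in RasV12, 84.6 in MekDD and 3.83 in AKTmyr, and BUB1 overlaps between all 5 lines.

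RasV12 versus MekDD asks what RAS changes beyond its MEK branch. ERK output was stronger in RasV12, with DUSP6 at 351 ± 50.5 against 84.6 ± 12.5 CPM and HMGA2 at 129 ± 14.3 against 47.7 ± 10.7 (SD, n = 3). MMP1 stood at 3500 ± 1480 against 87.9 ± 64.3 CPM and AREG, an EGFR ligand, at 3.43 ± 1.4 against 0.273 ± 0.14. KRT7 was higher at 1120 ± 367 against 32.9 ± 6.31, and MITF lower at 27.5 ± 3.26 against 65.5 ± 24.3.

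Of 23 ERK output genes 11 were higher and 0 lower, 14 and 0 over the list alone, and 15 and 1 with the block (median 0.87, camera, Benjamini-Hochberg adjusted p = 2.49e-06, adjusted p = 0.0412 with an estimated correlation, and 0.175 with an estimated correlation and the block). DUSP6 differed by log2 2.05 (SE 0.18), SPRY4 by 1.84 (SE 0.33) and HMGA2 by 1.44 (SE 0.28), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.78e-06, 0.00177 and 0.00329. FOSL1 and AURKA missed the test and passed with the block (log2 0.61 and 0.80, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0939 and 0.0629, with the block 0.0122 and 0.0424). Cytokines gave 8 higher and 1 lower among 20 (10 and 1 over the list alone), proteases 7 and 1 among 16 (10 and 4) and p53 targets 5 and 1 among 25 (5 and 1), with camera, Benjamini-Hochberg adjusted p = 1.13e-04, 0.00232 and 0.0327, and adjusted p = 0.577, 0.145 and 0.698 with an estimated correlation. FOXO targets gave 7 lower and 2 higher among 20 (10 and 2 over the list alone), YAP targets 4 and 0 among 16 (4 and 0), epithelial genes 8 and 3 among 19 (9 and 3) and pigment epithelium genes 4 and 0 among 17 (4 and 0), with camera, Benjamini-Hochberg adjusted p = 8.12e-04, 0.00232, 0.0314 and 0.034, and adjusted p = 0.338, 0.165, 0.448 and 0.448 with an estimated correlation. With the block 12 FOXO targets and 7 YAP targets were lower, proteases gave 10 higher and 3 lower, and p53 targets 7 and 2. Examples are IL1A (log2 5.66, SE 0.70), CDKN1A (1.57, SE 0.29), INSR (-1.26, SE 0.18) and AJUBA (-0.87, SE 0.14). Collagen genes missed the test and passed with the block (camera, Benjamini-Hochberg adjusted p = 0.089, 0.0324 with the block, and adjusted p = 0.792 with an estimated correlation and the block).

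The largest differences upward were MMP3 (log2 9.96, SE 2.05), LCE1F (ratio 266, 95% interval 90.5 to 1290), COL6A3 (log2 7.04, SE 0.67), AKR1C1 (6.66, SE 0.68) and POSTN (6.56, SE 1.02). Downward they were GALNT17 (ratio 677, 187 to 5600), CCL2 (log2 -7.82, SE 1.15), FAM110C (-7.08, SE 0.71), SFRP4 (-6.43, SE 1.27) and MTUS1 (-5.74, SE 0.36). Mitotic and replication lists did not pass, with medians from -0.10 to 0.17. Of the 11 tested chromosome Y genes, 8 were higher and 2 lower in RasV12 (median 5.08). They had camera, Benjamini-Hochberg adjusted p = 3.85e-06, and adjusted p = 0.186 with an estimated correlation. Against T53D4 their median was 0.12 in RasV12, with 0 higher and 0 lower, and -4.83 in MekDD, so the difference lay in the MekDD line. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 975 genes were higher and 1133 lower in RasV12, and 1700 and 1888 with the replicate block. Without MekDD replicate 3, 620 were higher, and without RasV12 replicate 2, 698 were lower. The construct gene list differed (4 higher and 1 lower of 7, camera, Benjamini-Hochberg adjusted p = 0.00232, and adjusted p = 0.233 with an estimated correlation), and the CDK4 construct went against the MekDD label, log2 4.07 (SE 0.16) higher in RasV12.

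RasV12 versus AKTmyr compares both lines labelled transformed. ERK output had the largest median difference of the 25 lists, with DUSP6 at 351 ± 50.5 against 3.83 ± 0.611 CPM and SPRY4 at 111 ± 33.7 against 0.548 ± 0.219 (SD, n = 3). MMP1 stood at 3500 ± 1480 against 0.243 ± 0.216. Basement membrane collagen COL4A1 was lower in RasV12, at 70.9 ± 15.8 against 2160 ± 1160, as was the glucose transporter gene SLC2A1, at 407 ± 117 against 1780 ± 288. AURKA, a spindle kinase, was higher in RasV12, at 159 ± 38.3 against 77.5 ± 23.5.

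Of 23 ERK output genes 19 were higher and 0 lower, 19 over the list alone (median 2.92, camera, Benjamini-Hochberg adjusted p = 1.04e-14, and adjusted p = 0.00169 with an estimated correlation). SPRY4 differed by log2 7.58 (SE 0.45), DUSP6 by 6.53 (SE 0.23) and ETV4 by 4.73 (SE 0.44), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.23e-07, 1.52e-09 and 4.16e-06. Ribosome biogenesis genes gave 21 higher and 0 lower among 26 (22 over the list alone), proteases 11 and 2 among 16 (11 and 2) and cytokines 11 and 1 among 20 (11 and 1), with camera, Benjamini-Hochberg adjusted p = 3.73e-08, 0.00392 and 0.00397, and adjusted p = 0.677, 0.194 and 0.678 with an estimated correlation. Glycolysis gave 15 lower and 1 higher among 29 (18 and 1 over the list alone), collagen 11 and 2 among 23 (13 and 2), class I presentation 9 and 0 among 17 (10 and 0) and FOXO targets 11 and 1 among 20 (13 and 2), with camera, Benjamini-Hochberg adjusted p = 3.41e-05, 0.0034, 0.00254 and 0.00551, and adjusted p = 0.677 with an estimated correlation in each. Examples are RRS1 (log2 1.94, SE 0.26), EGLN3 (-5.65, SE 0.74), COL5A1 (-7.43, SE 1.16), HLA-B (-1.75, SE 0.34) and FBXO32 (-1.89, SE 0.34). Without the replicate 1 libraries 23 glycolysis and 5 class I genes were lower.

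Some cell division genes differed. AURKA differed by log2 1.03 (SE 0.27), CDC20, the checkpoint's target, by 0.89 (SE 0.22) and BUB3 by 1.25 (SE 0.19), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.008, 0.00561 and 1.66e-04. AURKA lies on chromosome 20 and BUB3 on the long arm of chromosome 10, whose genes had medians of 0.23 (128 higher, 55 lower) and 0.29 (126 higher, 46 lower) in this comparison. Replication genes gave 6 higher among 37 (2 over the list alone), kinetochore 4 among 33 (0) and checkpoint 2 among 13 (2), with camera, Benjamini-Hochberg adjusted p = 0.00392, 0.0225 and 0.0405, and adjusted p = 0.717 with an estimated correlation in each. Spindle and cytokinesis genes gave 0 higher and 2 lower among 26 and mitotic kinases 4 and 2 among 27, and neither list passed (camera, Benjamini-Hochberg adjusted p = 0.209 and 0.132). Without the replicate 1 libraries the replication and checkpoint lists had 1 gene higher each, the spindle and kinase lists 1 and 2 lower, and the kinetochore list none. The first 3 lists then missed the test (adjusted p = 0.295, 0.31 and 0.278), as did the interferon list (9 lower and 3 higher among 26, camera, Benjamini-Hochberg adjusted p = 0.0457, adjusted p = 0.677 with an estimated correlation, and 0.259 without those libraries). With the replicate block the checkpoint and interferon lists missed the test as well. CDKN1A was lower in RasV12 (log2 -1.05, SE 0.28, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00914), a call lost without AKTmyr replicate 1 (0.0519).

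The largest differences upward besides MMP1 (log2 13.93, SE 0.88) were G0S2 and LCE1F, with no reads in AKTmyr and at least 459-fold and 330-fold higher, ESM1 (ratio 3600, 95% interval 646 to 142000) and PI3 (2720, 488 to 108000). GSTA1, CLEC19A and ITM2A had no reads in RasV12 and were at least 889-fold, 383-fold and 287-fold lower, and GALNT17 (ratio 2720, 752 to 22400) and ITIH5 (710, 243 to 3440) were lower too. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2669 genes were higher and 2821 lower in RasV12, 862 and 1525 of them by 2-fold or more. The cyclin D1 and CDK4 constructs were higher in RasV12 too (log2 1.45, SE 0.21, and 1.24, SE 0.15).

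MekDD versus AKTmyr compares the MEK and AKT branches. DUSP6 stood at 84.6 ± 12.5 CPM in MekDD and 3.83 ± 0.611 in AKTmyr, and SPRY4 at 31 ± 5.79 and 0.548 ± 0.219 (SD, n = 3). CDKN1A was lower in MekDD, at 165 ± 34 against 1020 ± 388, as were MMP2, at 3.02 ± 1.27 against 325 ± 128, and KRT7, at 32.9 ± 6.31 against 1540 ± 961. SERPINF1, the pigment epithelium factor gene, was higher at 26.3 ± 1.65 against 2.16 ± 0.607.

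Of 23 ERK output genes 18 were higher and 0 lower, 19 over the list alone (median 1.92, camera, Benjamini-Hochberg adjusted p = 1.75e-15, and adjusted p = 0.00136 with an estimated correlation). SPRY4 differed by log2 5.74 (SE 0.43), DUSP6 by 4.47 (SE 0.21) and FOSL1 by 1.37 (SE 0.23), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.15e-06, 7.56e-08 and 9.77e-04. Ribosome biogenesis genes gave 18 higher and 0 lower among 26 (22 over the list alone), with camera, Benjamini-Hochberg adjusted p = 3.78e-08, and adjusted p = 0.672 with an estimated correlation. Glycolysis gave 9 lower and 0 higher among 29 (15 over the list alone), collagen 10 and 1 among 23 (10 and 2), sterol synthesis 8 and 0 among 32 (8), p53 targets 8 and 0 among 25 (8) and class I presentation 5 and 0 among 17 (6), with camera, Benjamini-Hochberg adjusted p = 7.17e-06, 0.00549, 0.0016, 0.00562 and 0.00763, and adjusted p = 0.672, 0.682, 0.682, 0.672 and 0.682 with an estimated correlation. With the block 21 glycolysis genes were lower, and sterol and collagen genes gave 16 and 13 lower and 1 and 3 higher. Examples are CA12 (log2 -1.41, SE 0.21), COL5A1 (-6.85, SE 1.12), HMGCS1 (-1.36, SE 0.29), PHLDA3 (-0.94, SE 0.21) and TAP1 (-1.03, SE 0.22). Without the replicate 1 libraries 11 ribosome biogenesis genes were higher, and 16 glycolysis and 2 class I genes lower. Replication genes gave 7 higher among 37 (3 over the list alone, 15 with the block), kinetochore genes 0 among 33 (4 with the block) and interferon genes 9 lower and 3 higher among 26 (14 and 4), with camera, Benjamini-Hochberg adjusted p = 6.12e-04, 0.0498 and 0.00995, and adjusted p = 0.886, 0.962 and 0.672 with an estimated correlation. Without the replicate 1 libraries these 3 lists missed the test (adjusted p = 0.108, 0.363 and 0.108), with 2 replication genes higher and 5 interferon genes lower.

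Among the largest differences upward were MMP1 (log2 8.61, SE 0.77), ADGRL4 (ratio 334, 95% interval 114 to 1620), VAT1L (log2 6.61, SE 0.45) and SPRY4. Downward they were IGF1, with no reads in MekDD and at least 226-fold lower, ITIH5 (ratio 2200, 395 to 87000), GSTA1 (974, 333 to 4720) and HEPH (log2 -8.56, SE 0.54). Of the 11 tested chromosome Y genes, 8 were lower and 3 higher in MekDD (median -5.07). They had camera, Benjamini-Hochberg adjusted p = 4.91e-04, and adjusted p = 0.427 with an estimated correlation. CDKN2A missed the test and passed with the block (log2 0.39, SE 0.26, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.29, and 0.0149 with the block). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1728 genes were higher and 1832 lower in MekDD, and 2756 were higher with the replicate block. Without MekDD replicate 2 the counts were 1092 and 1179, without AKTmyr replicate 1, 1072 were higher, and the CDK4 construct was lower in MekDD, against its label (log2 -2.82, SE 0.16).

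**Figure D5:**
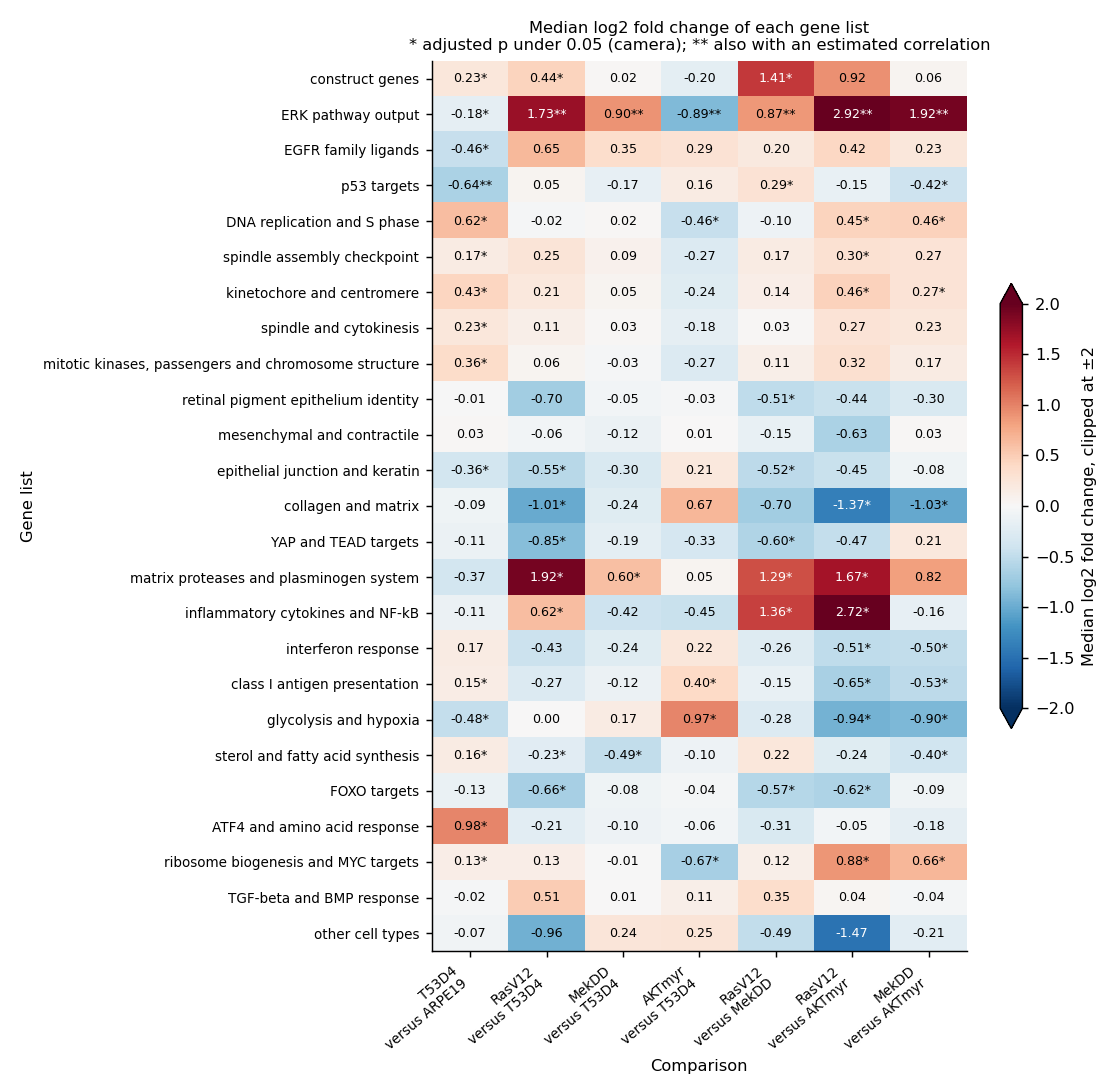
Median log2 fold change of each of the 25 gene lists (rows of the grid) in the 7 comparisons (columns), with 1 star for a camera call and 2 stars where it holds with an estimated correlation. ERK pathway output holds with an estimated correlation in 6 comparisons (medians 1.73, 0.90, -0.89, 0.87, 2.92 and 1.92), and the p53 targets in T53D4 versus ARPE19 (-0.64). With the replicate block added, the p53 targets lose this, as does ERK output in AKTmyr versus T53D4 and RasV12 versus MekDD.

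Overlap of the calls against T53D4 gives the calls that the oncogene lines share. RasV12 and AKTmyr both exceeded T53D4 in the cyclin D1 and CDK4 constructs, by log2 4.01 and 4.69, and 2.56 and 3.45. MekDD exceeded it by 0.89 and 0.62. In the shared calls, a response to the oncogenes cannot be told apart from this construct difference. RasV12 and MekDD shared 236 rises and 254 falls, against 33.3 and 52.3 for independent lists, and 18 genes were called in opposite directions. RasV12 and AKTmyr shared 284 and 383, against 145.2 and 188.9, with 320 opposite. MekDD and AKTmyr shared 85 and 127, against 30.6 and 39.4, with 85 opposite. Simulated unchanged lines sharing 3 simulated T53D4 libraries shared 0 calls in 20 simulations, which left out the pairing of replicate numbers. Lines without any change give few calls to share. The 0 therefore cannot show how many calls the shared controls add between lines that do differ from T53D4. The covariance of log2 fold changes across genes was 0.62, 0.216 and 0.148 for the 3 pairs, against 0.066 in the simulations of each, a difference of 0.554, 0.15 and 0.081. The correlations were 0.62, 0.21 and 0.21, against 0.50, 0.51 and 0.51 for unchanged lines. Unchanged lines vary by error alone, while the real lines add changes of their own that alter the correlation. The 2 sets of correlations therefore cannot be compared, and no conclusion is drawn from them. The 3 T53D4 libraries cannot be split with at least 2 in each part, so part of the excess may come from the shared controls, and genes are not independent replicates. With the replicate block 1075, 1251 and 569 calls were shared in the same direction, and without T53D4 replicate 2 it was 276, 433 and 116, against 490, 667 and 212.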

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

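Among the genes and lists picked by the naming rule, these were called at 2-fold or more (lists by camera) in opposite directions in a pair of oncogene lines against T53D4, with a called direct difference between the lines (edgeR quasi-likelihood, Benjamini-Hochberg adjustment). Over all genes, 13, 135 and 54 were called at 2-fold or more in opposite directions for RasV12 and MekDD, RasV12 and AKTmyr, and MekDD and AKTmyr, and only named ones are described. The libraries labelled T53D4 hold less cyclin D1 and CDK4 construct signal than RasV12 and AKTmyr, so the direct difference is given beside the opposite directions. It comes from the same fit and follows from the 2 values against T53D4, so it is no separate check. Direct differences with MekDD span these constructs too. RasV12 exceeded MekDD by log2 3.12 and 4.07, and MekDD differed from AKTmyr by -1.67 and -2.82.

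Between RasV12 and AKTmyr, ERK pathway genes parted. The ERK output list had medians of 1.73 in RasV12 and -0.89 in AKTmyr, and 2.92 directly. SPRY4 stood at log2 5.28 and -2.30 and differed by 7.58 (SE 0.45), DUSP5, an ERK phosphatase, at 2.19 and -2.18 and by 4.37 (SE 0.32), and ETV4, an ETS factor, at 2.24 and -2.49 and by 4.73 (SE 0.44). So did BMP2, a growth factor gene, at 3.68 and -1.24 (difference 4.92, SE 0.19) and VAT1L at 3.31 and -4.25 (7.56, SE 0.45). TWIST2 (7.34, SE 1.21) had no reads in AKTmyr and was at least 21.6-fold higher in RasV12, and its fall in AKTmyr had adjusted p = 0.0498.

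The named genes lower in RasV12 were these. MMP2 stood at -1.52 in RasV12 and 3.17 in AKTmyr (difference -4.69, SE 0.41), SPARC at -1.29 and 1.47 (-2.76, SE 0.39), EGLN3 at -2.83 and 2.82 (-5.65, SE 0.74), ALDH1L2, a folate enzyme, at -1.25 and 2.17 (-3.43, SE 0.29) and IFI27 at -1.97 and 2.04 (-4.01, SE 0.53). ITIH5 had few reads in RasV12, so its -9.20 is better given as a ratio of 710 (95% interval 243 to 3440).

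Between MekDD and AKTmyr the ERK output list had medians of 0.90 and -0.89, and 1.92 directly. SPRY4 stood at 3.44 and -2.30 (difference 5.74, SE 0.43), BMP2 at 1.70 and -1.24 (2.93, SE 0.17), VAT1L at 2.36 and -4.25 (6.61, SE 0.45) and SERPINF1 at 1.73 and -1.86 (3.59, SE 0.28). ADGRL4 (8.17) had few reads in AKTmyr and a ratio of 334 (95% interval 114 to 1620). MMP2 stood at -3.57 and 3.17 (-6.74, SE 0.46) and SESN3, a FOXO target, at -1.74 and 1.63 (-3.37, SE 0.42). ITIH5 (-10.57) had few reads in MekDD and a ratio of 2200 (395 to 87000). Between RasV12 and MekDD SESN3 was the only named gene that parted, at 1.70 and -1.74 (difference 3.43, SE 0.43).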

How the results depend on the processing

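Most named results kept their direction and side of the test. Of 519 gene results, 519 were unchanged with construct reads kept, 517 with robust dispersion, 514 with RLE size factors, 514 with DESeq2, 512 with the replicate block, 511 without the low-count filter and 489 with a CPM filter. With 2 groups only 56 missed the test, without the replicate 1 libraries 66, and against 1.5-fold with glmTreat 150, since that test asks for more. Leaving out single libraries gave 2664 unchanged results and 440 that missed the test, with fewer samples. Of 175 list results, 167 were unchanged with the block, 133 with fry and 119 with an estimated correlation. Ribosome biogenesis in T53D4 versus ARPE19 reversed without the replicate 1 libraries (camera, Benjamini-Hochberg adjusted p = 0.63), and the cause was not tested. Depth of 20.63 to 46.55 M reads limits genes with few reads, and 3 libraries per line limit all tests.

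Counts for T53D4 versus ARPE19 moved most, from 5 higher and 16 lower to 1 and 1 with 2 groups only, 101 and 131 with the replicate block, 79 and 113 with DESeq2, 2 and 5 without the replicate 1 libraries, and 1 and 0 with glmTreat. The 0 from glmTreat stands beside 258 genes with an unadjusted p under 0.05 in that test, and beside 113 lower with DESeq2. Single libraries left out gave 1 to 3 higher and 0 to 5 lower. The cause was not tested, except that glmTreat sets a higher bar.

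For RasV12 versus T53D4 the block gave 2259 higher, glmTreat 514 and 815, and single libraries left out 1083 to 1266 higher and 1410 to 1656 lower. For MekDD versus T53D4 the block gave 746 and 843, DESeq2 498 and 629, glmTreat 118 and 172, and single libraries left out 170 to 277 and 190 to 323. For AKTmyr versus T53D4 the block gave 2304 and 2434, 2 groups only 788 and 661, glmTreat 276 and 282, leaving out the replicate 1 libraries 816 lower, and single libraries left out 812 to 1359 and 793 to 1310. For RasV12 versus MekDD the block gave 1700 and 1888, glmTreat 328 and 398, and single libraries left out 620 to 920 and 698 to 996. For RasV12 versus AKTmyr glmTreat gave 801 and 1271, and single libraries left out 2023 to 2758 and 2225 to 2919. Same-numbered libraries of those 2 lines correlated at 0.25, 0.34 and 0.03. The last pair stayed under the pairing threshold of 0.1, which does not show that the lines are unpaired. The block there gave 3578 and 3585, with the checkpoint and interferon lists missing the test (camera, adjusted p = 0.0616 and 0.0724). For MekDD versus AKTmyr the block gave 2756 higher, 2 groups only 1100 higher, glmTreat 427 and 579, and single libraries left out 1072 to 1774 and 1179 to 1924. Apart from glmTreat and fewer samples, the cause was not tested.

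Gene lists called fell to 1 in each of the 7 comparisons with an estimated correlation, from 15, 9, 3, 5, 9, 12 and 10. With fry T53D4 versus ARPE19 had 3, and without the replicate 1 libraries AKTmyr versus T53D4 had 8. Chromosomes called by camera fell to 0 with an estimated correlation in RasV12 versus T53D4, MekDD versus T53D4 and RasV12 versus MekDD, from 2 each, and in RasV12 versus AKTmyr and MekDD versus AKTmyr, from 1 each. Shared calls of RasV12 and MekDD were 775 with DESeq2, 1075 with the block and 276 to 383 with single T53D4 libraries left out. Those of RasV12 and AKTmyr were 301 at 2-fold or more, 1251 with the block and 433 to 475 with single T53D4 libraries left out. Those of MekDD and AKTmyr were 134 at 2-fold or more, 360 with DESeq2, 569 with the block and 116 to 152 with single T53D4 libraries left out. The correlation estimated from the residuals exceeded the preset value in every list but the markers of other cell types. It was lowest among those lists for the proteases, at 0.0297, and it was -0.0634 for the markers of other cell types. A higher correlation between members widens a list's error. For the chromosomes and the other alternatives the cause was not tested.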

Other observations

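All tests on the constructs, the copy number test and both replication list tests were chosen after the result was seen. The splits of libraries were written first. The tests of chromosome 10 on GC content, reference and single libraries were written before their own results, but after the arm pattern had been seen.

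Reads on the cyclin D1 construct were at least 0.723 times those on the CCND1 gene in every RasV12 and AKTmyr library, against at most 0.25 in ARPE19, which argues against a rise of the cell's own CCND1 as the only source. At least 1870 reads of the murine p53DD construct in each T53D4 library argue against ARPE19 cells under another name. A plasmid that is silent or missing in T53D4 may explain a CDK4 construct 1.3 times the ARPE19 level, and these data cannot part the alternatives.

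The difference between the arms of chromosome 10 in RasV12, 0.63 by medians, was 0.69 with the replicate block after a smooth trend on GC content and exon length was removed, and at least 0.62 against every other line. The lowest value in 1 RasV12 library was 0.47. These values argue against GC content, the T53D4 reference and a single library. Of 780 equally long stretches on other chromosomes, 0% had a median as far from 0 as the short arm, but the arm was chosen for its values, so this is no independent test. A changed number of arm copies in the RasV12 line is a hypothesis that could account for the difference and stays open, since no DNA was measured.

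The DNA replication list exceeded ARPE19 in T53D4 by at least 0.43 in pairs 2 and 3, which argues against the replicate 1 batch as the only source. Its median spanned 0.98 among the ARPE19 libraries, so growth state of single cultures may contribute and stays open.

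Each pair of lines allows 10 splits of its 6 libraries, too few for a share under 0.05. For genes, the real split called 21, 3313, 694, 2738, 2108, 5490 and 3560 in the order of the report, and the other splits at most 0. The 1 split of 10 that called as many each time was the real one. Every other split puts both lines in each part, so line differences count as spread, and no conclusion is drawn from the 0. For lists, the real split called 15, 9, 3, 5, 9, 12 and 10, and the highest other split 14, 13, 12, 13, 16, 14 and 15. With the real one included, 1, 4, 9, 10, 2, 2 and 4 splits called as many. Among splits parting 3 pairs, as the real one does, the highest were 14, 13, 12, 11, 16, 14 and 15. In MekDD versus T53D4 another split called 12 lists against 3 for the real one. Outside T53D4 versus ARPE19 the real split did not call the most lists. The number that camera calls with its preset correlation therefore does not set the real grouping apart there. Each part of the other splits mixes both lines unevenly. These splits keep line and replicate differences, so they do not show what unchanged groups would give, and the cause was not tested.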
